A study of Mus musculus with 4 samples.

How the data were processed

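Single-cell RNA sequencing was done on hematopoietic stem and progenitor cells (HSPCs) of donor origin, recognised by the CD45.2 form of the leukocyte antigen CD45 and sorted from the bone marrow of C57BL/6 mice 20 weeks after competitive transplantation. Per the labels' protocols, 20000 sorted cells per sample entered droplet capture with the 10x Genomics 3' v3.1 chemistry, without multiplexing. The labels name 4 samples, 2 from wild-type donors and 2 from donors with a heterozygous Srcap mutation, and call each sample independent. They do not say which change the Srcap allele carries.

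The authors deposited whole-number UMI counts per gene and cell in a single aggregated matrix of 32285 genes and 44151 cell barcodes. The matrix was made with Cell Ranger 6.1.2, per the file headers, and the mm10 build is given in the submitters' processing notes. The counts carried no scaling per cell. Whether depth was evened out between libraries at aggregation cannot be read from whole-number counts. Each barcode ends in a suffix from 1 to 4, which separates 4 libraries, but no label used here ties a suffix to a sample. Cells therefore could not be assigned to wild type or mutant, and the order of the suffixes, the cell numbers and the level of Srcap were not used to guess the assignment. The edgeR comparison of mutant with wild type that had been planned was not run, and DESeq2, the replicate block and the fits without single replicates fell away with it. The barcode suffixes are called library 1 to library 4 below. Their values are given one by one or as a median and range, with no mean, SD or p-value, because libraries of unknown genotype are not replicates of a group. No group holds enough samples for a test of outlying samples.

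Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept. Doublets were called per library with Scrublet as run by Scanpy 1.11.5, at an expected rate of 8%. The automatic thresholds marked 2, 3, 1 and 0 cells in libraries 1 to 4, fewer than a working caller would mark among this many cells, so doublets were in effect not removed. An alternative without the highest 8% of doublet scores in each library was added after seeing this. The filters and the doublet calls left 41116 cells and removed 3035 barcodes.

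So that no gene that defines a cluster is reported as a result, the genes other than the cell type markers were split at random (seed 1) into a clustering set and a described set. All members of the 22 fixed gene lists that were not markers went into the described set, and the markers went into the clustering set. Counts were scaled to 10000 UMIs per cell and log-transformed, 2000 variable genes were taken from the clustering set, and 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2, resolution 1, seed 0) gave 26 clusters. Genes of 1 program vary together, so the described set is not independent of the cluster borders. Clusters were named from 15 marker sets fixed before the data were examined. A cluster took the name of the set with the highest median fold if the median log2 fold was at least 1, at least 3 markers were 2-fold higher, and no other set had more genes among its top 10. A cluster also stayed unnamed if its median UMI count was under 0.333 times that of its libraries and no marker of that set stood among its top 10 genes. These thresholds were set after the clusters had been seen. They left 6 clusters, called progenitor by default, and 2 clusters of low UMI counts without a name. Of these 2, the larger was led by B cell genes such as Ms4a1 and Ighd and the smaller by hemoglobin genes. The 6 progenitor clusters held 36.2% to 50.1% of the cells of a library.

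For each class contrast, UMIs were summed per library and class, scaled to the library and class total as CPM, and the log2 ratio of CPM plus 1 was taken within each library. That scale understates the ratio of genes with few counts. For the 12 highest and 12 lowest genes, UMI counts replace the ratio where the lower side held at most 3 UMIs in a library. Genes with at least 5 CPM averaged over both sides entered the gene lists. The median of a list was placed among 10000 random lists of the same size matched on mean expression. This percentile describes these libraries and is not a p-value. A list member was counted as higher or lower when it differed by at least 1.5-fold in the same direction in every library, which is a rule of size and not a test. Named genes were, per contrast, the 12 highest and the 12 lowest of the described set at 50 CPM or more on the higher side, ranked by the library closest to 0 and leaving out ribosomal protein genes, mitochondrial genes and unnamed gene models. Examples from the lists and Srcap were also named. The clusters of the lymphoid-primed-like class were compared one by one after the data were examined. Some single genes are not reported here. The planned second side of 2 contrasts was a granulocyte-monocyte-progenitor-like class. No cluster took that name, and the neutrophil-like and monocyte-progenitor-like clusters were used in its place, a choice made after the data were examined. The neutrophil-like cluster had 5 of its own markers among its top 10 genes. It also had 3 markers of the granulocyte-monocyte progenitor set there, Cebpe, Elane and Fcnb, so its name is not secure.

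The list and ratio steps were tested on simulated counts before use. With each side at 10% of the depth of a library, 200 of 1449 genes were changed. The median log2 ratio was 0.99 for the 50 genes raised 2-fold and 0.57 for the 50 genes raised 1.5-fold, and all 50 genes of each kind had the right sign in every library. No unchanged gene reached 1.5-fold in every library, and 2 of 100 lists of unchanged genes fell outside the middle 95% of random lists. The changed genes and the 1.5-fold check covered genes at 50 CPM or more only, while the lists take genes from 5 CPM. Counts were independent Poisson draws, with no spread between cells and no genes that vary together. The simulation therefore does not cover these features of the real lists.

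Shares carry exact Clopper-Pearson 95% intervals and single-gene CPM values exact Poisson 95% intervals. Both cover counting error only. Positions are from GENCODE M21 on GRCm38, the assembly also called mm10, in which 32235 of the 32285 gene identifiers were found. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0. Alternatives were Leiden resolutions of 0.5 and 2, doublets kept, a second random split of genes, a mitochondrial limit of 5%, at least 1000 genes per cell, a pseudocount of 5 CPM, a gene filter at 20 CPM or none, median-of-ratios scaling, each library left out in turn, and, added after seeing the data, the doublet score limit and a restriction to cells with fewer than 10 S and G2/M phase UMIs per 10000.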

Results

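Donor HSPCs from recipients of wild-type or Srcap heterozygous mutant marrow were profiled by single-cell RNA sequencing 20 weeks after competitive transplantation, an assay in which donor and competitor cells rebuild the blood system of the same recipient. Srcap encodes the ATPase of a chromatin remodelling complex that places the histone variant H2A.Z into nucleosomes. The 4 libraries held 13301, 10879, 10460 and 9511 barcodes and 144385614, 121282354, 119134008 and 112027160 UMIs, in the order of the barcode suffixes. After filtering, 12416, 10025, 9649 and 9026 cells were kept, with a median of 9823, 10224, 10225 and 10053 UMIs per cell. Because the suffixes are not tied to samples, the comparison of mutant with wild type is not analysed here. The comparisons given are those between cell classes of the same library, which do not need the genotype, and the values of each unlabelled library.

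Srcap transcripts were detected in every library and in every cell class. Over all kept cells, Srcap (ENSMUSG00000053877, chromosome 7, 127511983 to 127561219 on the forward strand of GRCm38) stood at 58.7 CPM in library 1 (95% Poisson interval 57.5 to 60.0), 81.6 CPM in library 2 (79.9 to 83.2), 52.7 CPM in library 3 (51.4 to 54.0) and 53.2 CPM in library 4 (51.9 to 54.6). In HSC-like cells, the class with the markers of hematopoietic stem cells, the levels were 63.7, 81.8, 54.6 and 58.6 CPM. The ratio of HSC-like to other progenitor-like cells was close to even, with a median log2 ratio of 0.03 and a range of -0.05 to 0.07. Srcap was higher in lymphoid-primed-like than in neutrophil- and monocyte-progenitor-like cells in 4 of 4 libraries (median log2 ratio 0.66) and higher in megakaryocyte- and erythroid-like cells in 4 of 4 libraries (0.62). The lowest levels among named classes were those of plasma cell-like cells, at 14.6, 31.3, 21.6 and 19.1 CPM. Immunoglobulin genes led that class, Ighm alone at 103529 CPM, which lowers the CPM of other genes there. A 3' tag does not read the altered part of an allele unless the change lies there, so these levels do not check the genotype. Library 2 also held higher levels of long genes in general.

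Most kept cells fell into stem- or progenitor-like classes or into the set without a class name. That set was defined by failing the naming rule and not by progenitor markers. The largest set was progenitor-like cells without a class name, at 49.8%, 50.1%, 47.3% and 36.2% of kept cells. It included clusters led by S phase, histone and G2/M phase genes. It also held a cluster led by hemoglobin genes (12.6%, 3.64%, 13.5% and 8.75%). Another of its clusters had 4 HSC markers at least 2-fold higher (5.39%, 12.8%, 5.25% and 5.22%). In library 2 the hemoglobin cluster had its smallest share and the cluster with HSC markers its largest. HSC-like cells made up 11.3% of library 1 (95% interval 10.8 to 11.9), 11.3% of library 2 (10.7 to 11.9), 13.9% of library 3 (13.2 to 14.6) and 24.2% of library 4 (23.3 to 25.1). Cells like lymphoid-primed multipotent progenitors, an early stage with access to lymphoid and myeloid fates, made up 14.99%, 16.5%, 15.2% and 11.9%, and megakaryocyte-like cells 10.5%, 9.46%, 9.46% and 12.4%. The median share was 3.42% for B lineage-like, 2.24% for neutrophil-like, 1.98% for dendritic cell-like, 1.30% for erythroid-like, 1.03% for monocyte-progenitor-like and 0.520% for basophil- or mast cell-like cells. The plasma cell-like share was 0.838%, 0.898%, 1.17% and 2.03% and the macrophage-like share 0.636%, 0.569%, 0.415% and 0.199%. T, NK or innate lymphoid-like cells had a median of 0.910% and low-UMI clusters without a name 0.815%. The intervals cover counting error only, and the sort can set shares. The lymphoid-primed-like share depended on the clustering, with a median of 15.1% at resolution 1 and 1.49% at resolution 0.5. No cluster took the monocyte progenitor name at resolution 0.5 or with the second split of genes, where the neutrophil-like median was 3.47% and 3.87%. The second split also gave 0.295% for basophil- or mast cell-like cells.

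**Figure D1:**
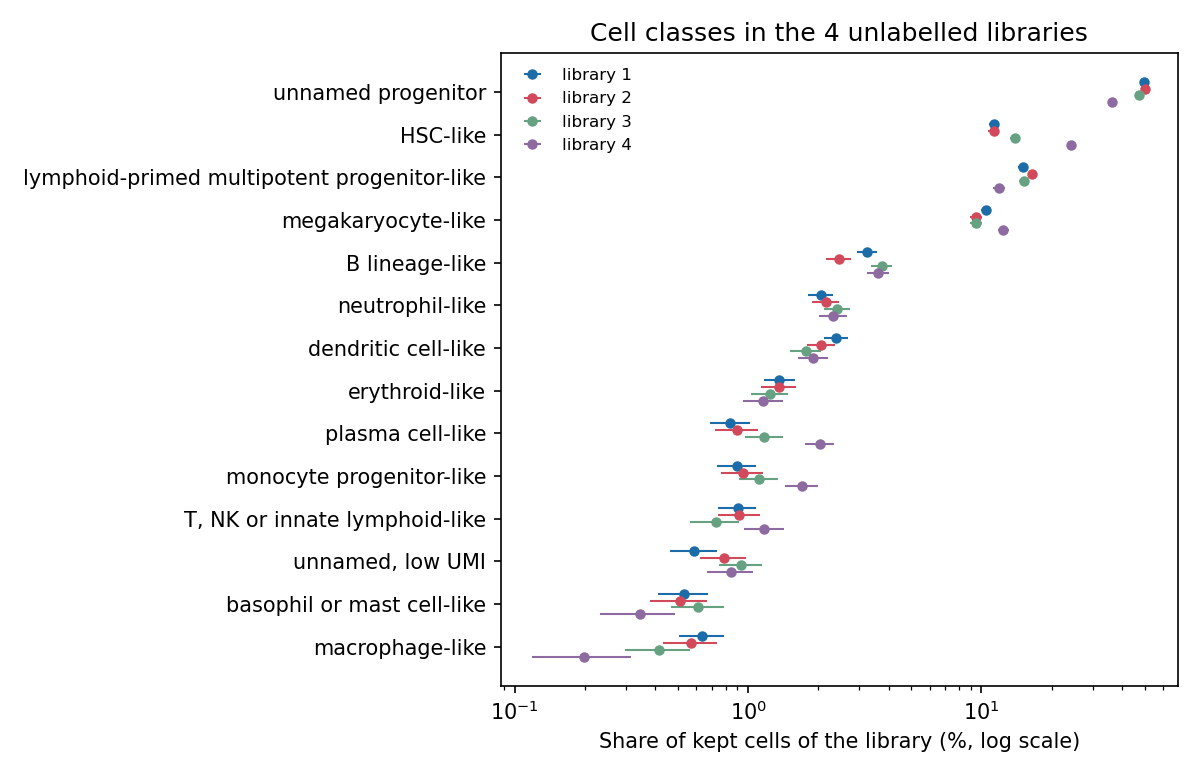
Share of kept cells (percent, log scale) of each cell class in the 4 libraries, named by barcode suffix and not tied to a genotype; bars are exact 95% binomial intervals, which cover counting error only. The HSC-like share of library 4, 24.2%, lies above the 11.3% to 13.9% of the other libraries.

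The first class contrast asked which programs set the stem cell end of the population apart from the other progenitors of the same library. That other side joined the unnamed progenitor-like, lymphoid-primed-like, megakaryocyte-like, erythroid-like, monocyte-progenitor-like and basophil- or mast cell-like cells. Neutrophil-like cells, the remaining named classes and the low-UMI clusters were left out, a choice made after the clusters had been seen. Genes of cell division were far lower in HSC-like cells, in part by construction. Clusters led by S phase, histone and G2/M phase genes took no class name and were placed among the other progenitor-like cells. A cycling stem cell that fell into these clusters was therefore not counted as HSC-like. All 28 measured G2 and M phase genes and all 28 measured S phase genes were at least 1.5-fold lower in 4 of 4 libraries, with list medians of -4.17 and -2.22 on the log2 scale and ranges over libraries of -4.35 to -3.86 and -2.49 to -1.98. Mki67, a marker of cycling cells (chromosome 7, 135689784 to 135716361), stood at 4 to 12 CPM in HSC-like and 343 to 638 CPM in other progenitor-like cells, a median log2 ratio of -5.70. The spindle and mitosis genes Ube2c (-5.43), Birc5 (-5.30), Hmmr (-5.26), Cenpf (-5.05), Nusap1 (-4.96), Kif11 (-4.80), Aurkb (-4.52) and Ccnb2 (-4.50), the histone genes Hist1h1b (-5.57) and Hist1h2ab (-4.92), whose products are made in S phase, and Ckap2l (-4.74) completed the 12 lowest. In the S phase list, Tk1 (-4.57), Mcm10 (-3.62) and Rrm2 (-3.62) were lowest.

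Some DNA repair lists were also lower in HSC-like cells. Of 24 measured genes of homologous recombination and the Fanconi anemia pathway, 16 were at least 1.5-fold lower and none higher in 4 of 4 libraries, with a list median of -1.19 (range -1.28 to -1.10), below every matched random list in every library. Brca1 (-3.49) and Fancd2 (-2.80) were among them. DNA damage signalling had 6 of 16 members lower and none higher (median -0.55), including Clspn (-3.62) and Chek1 (-2.50), and mismatch and excision repair 7 of 29 lower and none higher (median -0.41), including Neil3 (-4.28) and Exo1 (-2.76). Non-homologous end joining had 2 of 10 lower (median -0.08, inside the middle 95% of random lists in every library). Among cells with few S and G2/M phase UMIs, the homologous recombination and Fanconi anemia median was -0.04, that of DNA damage signalling -0.03 and that of mismatch and excision repair -0.15. The end joining median turned to 0.10 with the gene filter at 20 CPM, which moved the homologous recombination and Fanconi anemia median to -0.66. Few such UMIs were found in 78.1% to 90.2% of HSC-like and 21.2% to 28.1% of the other progenitor-like cells.

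The 12 genes with the highest ratio in HSC-like cells were Sult1a1, a sulfotransferase (median log2 ratio 4.30, chromosome 7, 126672865 to 126676432), Gda (3.56), Tgm2 (2.91), Hacd4 (2.41), the MYC family member Mycn (2.45), Cdkn1c (2.38), Myof (2.26), Nkx2-3 (1.94), Mmrn1 (2.26), Itsn1 (1.79), Bex1 (1.99) and Cd74 (2.44), the invariant chain of MHC class II. Sult1a1 stood at 61 to 107 CPM against 2 to 5 CPM. Of 15 measured quiescence and cell cycle inhibitor genes, 7 were higher and 2 lower (median 0.60). Ndn (2.83), Cdkn1c, Egr1 (1.78) and Txnip (1.60) were higher, while Cdkn1a (-1.64) and Btg2 (-1.16) were lower. Of 21 interferon response genes, 10 were higher and none lower (median 0.67), with Ifit1 (1.49) and Igtp (1.39) as examples, and of 15 MHC genes 4 were higher (median 0.44), led by Cd74, H2-Eb1 (2.11) and H2-Aa (2.02). Immediate early and heat shock genes, which respond to cell handling, were also higher, 6 of 13 (median 0.64), among them Junb (1.27) and Jun (1.02). The summed level of the list was not higher, at 1533 to 1736 CPM in HSC-like and 1592 to 1799 CPM in unnamed progenitor-like cells, and its most abundant member, Hsp90aa1 (-0.61), was lower. Each of the 4 list medians lay at or above 99.9% of matched random lists in every library. In cells with few S and G2/M phase UMIs the quiescence median was -0.07, the interferon median 0.28, the MHC median 0.29 and the immediate early median 0.16. With the gene filter at 20 CPM the quiescence median was 0.09.

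Oxidative phosphorylation and MYC and ribosome biogenesis genes were lower in HSC-like cells. Nuclear-encoded oxidative phosphorylation genes had 13 of 28 members lower and none higher (median -0.60), including Cycs (-1.47) and Cox5a (-1.17), and MYC and ribosome biogenesis genes a median of -0.42 with 3 of 20 lower and Mycn alone higher. The SRCAP complex and H2A.Z list had 4 of 13 members lower and none higher: H2afz (-1.79) and H2afv (-1.23), which encode H2A.Z, Anp32e (-1.11), an H2A.Z chaperone, and Actl6a (-0.77). Its median, -0.25, lay inside the middle 95% of random lists in every library. Genes recurrently mutated in clonal hematopoiesis had 4 of 20 lower (median -0.24), among them Ezh2 (-2.07) and Chek2 (-0.96), and other chromatin remodelling genes 2 of 22 higher, Chd7 (2.42) and Smarca2 (0.97), and 1 lower (median -0.10). The lymphoid priming median was -0.42, with Ly6d (-3.61) and Il7r (-2.97) lower and Gata3 (1.49) and Foxo1 (1.27) higher. Medians were 0.23 for p53 target genes, 0.13 for myeloid regulators, -0.09 for glycolysis, -0.35 for RNA splicing, -0.23 for apoptosis regulators and 0.00 for histone and DNA modifying enzymes, in which Dnmt1 (-1.77) was lower and Ezh1 (0.92) higher. In cells with few S and G2/M phase UMIs, oxidative phosphorylation was at -0.24, MYC and ribosome biogenesis at -0.12, splicing at -0.15, lymphoid priming at -1.03, p53 targets at -0.12 and myeloid regulators at -0.22. Single genes of these lists, such as H2afz, Ezh2 and Dnmt1, were not examined in those cells. Their difference was therefore not set apart from the difference in cycling. Each class pair rests on 8385950 to 18326397 UMIs of HSC-like and 76362991 to 114808351 UMIs of other cells per library. Clusters were drawn from the same cells, so the contrast describes classes and tests no hypothesis.

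**Figure D2:**
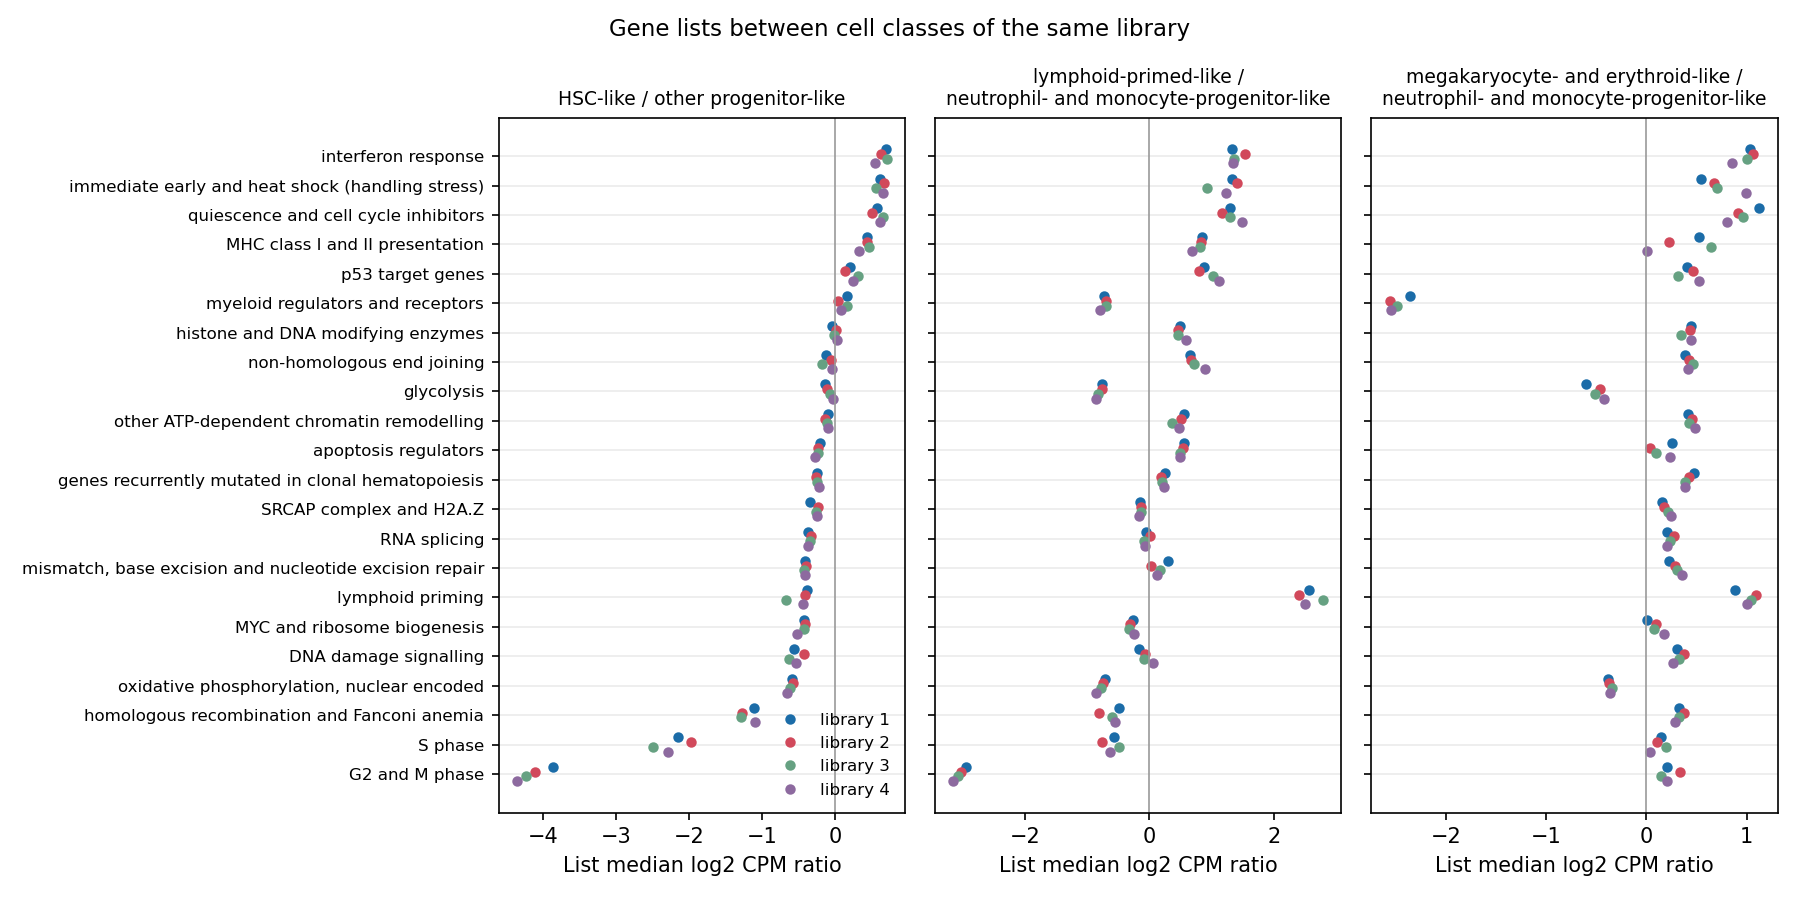
Median log2 CPM ratio of each gene list between 2 cell classes of the same library, 1 point per library (barcode suffix) and 1 panel per contrast; the vertical line marks no difference and the points carry no error bars. In the left panel the G2 and M phase medians lie between -4.35 and -3.86, the lowest of the 22 lists.

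The second contrast set lymphoid-primed-like against neutrophil- and monocyte-progenitor-like cells, the lymphoid and myeloid arms of the population. Lymphoid priming genes were higher in 13 of 14 measured members, with a median log2 ratio of 2.53 (range 2.40 to 2.79). Ly6d, a surface antigen of lymphoid progenitors (chromosome 15, 74762056 to 74763620), at 955 to 1969 UMIs per library against 1 to 106, Il7r (4.35), the receptor of interleukin 7, Bcl11a (2.26) and the recombinase gene Rag2 (2.83) were among them. The class joined 3 clusters, and the smallest, with 10.5% of its cells, had a lymphoid priming median of 4.25 and medians of 316 CPM of Il7r, 918 CPM of Ly6d and 62.3 CPM of Rag2. Rag1 stood there at 158 CPM and Blnk at 71.7 CPM, against 109 and 302 CPM in B lineage-like cells, and none of the markers of the class was among its top 10 genes. The name of the class, that of an early stage, is therefore not secure for this cluster. The largest, with 69.9% of the cells, had a list median of 1.82 and 8.53, 7.02 and 6.01 CPM of these genes, and the remaining cluster 1.58 and 23.3, 36.9 and 9.80 CPM. In library 1, Ly6d stood at 6.78 CPM in the largest cluster and at 4.57 CPM on the myeloid side. The median of the class was 4.34 at resolution 0.5 and 1.67 at a pseudocount of 5 CPM, and that of myeloid regulators -1.12 at resolution 0.5. Myeloid regulators and receptors had 8 of 18 lower and 2 higher (median -0.71), including Fcgr3 (-5.18), Cebpd (-2.21) and Csf1r (-1.91). The 12 highest were Arpp21 (4.35), Myl10 (4.37), Ly6d, Gimap6 (3.98), Cox6a2 (3.96), Ltb (4.16), Pglyrp2 (3.51), H2-Ob (3.59), Calcrl (3.00), Stxbp4 (3.25), Lsp1 (2.97) and Tsc22d1 (2.73), and the lowest were the granulocyte genes Wfdc21, Hp (-6.04) and Trem3 (-5.84), then Clec4a2, Cldn15, Fcgr3, Ube2c (-5.03), Hmmr (-4.66), Hist1h1b (-4.67), Birc5 (-4.20), Nusap1 (-4.17) and Hist1h2ab (-4.14). Lymphoid-primed-like cells held 0 to 9 UMIs of Wfdc21 per library against 618 to 1143, 3 to 5 UMIs of Clec4a2 against 392 to 577 and 2 to 8 UMIs of Cldn15 against 412 to 550.

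Interferon response genes were higher in the lymphoid-primed-like cells in 16 of 20 members (median 1.36), for example Ifit1 (2.75), Oasl2 (2.61) and Irf7 (2.33). Quiescence genes were higher in 9 of 11 (median 1.29), p53 target genes in 7 of 13 (median 0.95), with Trp53inp1 (3.23) and Sesn1 (2.28), MHC genes in 8 of 14 (median 0.83) and immediate early genes in 8 of 13 (median 1.29). The immediate early median was 0.44 with no gene filter, and the p53 target median 0.47 with the filter at 20 CPM. The summed immediate early and heat shock level was 1457 to 1640 CPM in lymphoid-primed-like, 1433 to 1609 CPM in neutrophil-like and 1555 to 1839 CPM in monocyte-progenitor-like cells. Chromatin genes showed medians of 0.50 for other remodelling factors, with Chd3 (2.14) higher and Chd7 (-3.22) lower, and 0.48 for histone and DNA modifying enzymes, of which 12 of 31 were higher, Tet1 (2.17) and Kdm6b (1.75) included. End joining genes had 5 of 11 higher (median 0.69), among them Xrcc5 (1.71) and Xrcc6 (1.51). The end joining median lay inside the middle 95% of random lists in libraries 1, 2 and 3 and above it in library 4. Oxidative phosphorylation (16 of 28, median -0.77) and glycolysis (8 of 14, median -0.80) genes were lower. The S phase median was -0.60 and the homologous recombination and Fanconi anemia median -0.58, with 12 of 29 and 9 of 26 lower. At resolution 2 they were -0.17 and 0.02, and with the marked doublets kept the latter was -0.03. The remaining medians were -0.14 for SRCAP complex and H2A.Z genes, 0.21 for clonal hematopoiesis genes, 0.14 for mismatch and excision repair, -0.08 for DNA damage signalling, -0.29 for MYC and ribosome biogenesis, -0.07 for splicing and 0.52 for apoptosis regulators. At resolution 2 the medians of SRCAP complex and H2A.Z genes (0.07), DNA damage signalling (0.15) and splicing (0.10) lay above 0, and that of MYC and ribosome biogenesis was -0.09. The median of all described genes was itself 0.15 to 0.19 in this contrast. The G2 and M phase median, -3.06 with all 28 members lower, turned when clusters were redrawn, to 0.16 with the 6 marked doublets kept and 0.09 at a mitochondrial limit of 5%.

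The third contrast set megakaryocyte- and erythroid-like against neutrophil- and monocyte-progenitor-like cells. Myeloid regulators and receptors were lower in 13 of 17 members, with a median of -2.52 (range -2.56 to -2.36), among them Fcgr3 (-6.32, from 4 to 10 UMIs per library on the lower side), Tyrobp (-5.04), Cebpd (-4.69) and Cebpa (-4.17). The 12 highest genes held several of the platelet lineage: Cavin2 (6.03, chromosome 1, 51289126 to 51302960), Rab27b (5.16), the thrombin receptor gene F2r (4.42), Mmrn1 (4.61) and the transcription factor gene Gfi1b (4.48), beside Mycn (4.55), Bex4 (4.30), Apoe (4.29), Hemgn (3.90), Lat (3.72), Gnb4 (3.35) and Plxnc1 (3.34). Apoe stood at 766 to 1005 CPM against 42 to 44 CPM. The 12 lowest were Hp, Trem3, Fcgr3, Wfdc21, Anxa3 (-5.96), Cldn15, Tifab, Pglyrp1 (-5.05), Clec4a2, Tyrobp, Hk3 (-4.68) and Cebpd. Megakaryocyte- and erythroid-like cells held 2 to 20 UMIs of Hp per library against 1969 to 3629, 3 to 4 UMIs of Trem3 against 1236 to 1864 and 1 to 2 UMIs of Cldn15 against 412 to 550. They held 2 to 9 UMIs of Wfdc21 against 618 to 1143, 2 to 6 UMIs of Tifab against 419 to 794 and 1 to 14 UMIs of Clec4a2 against 392 to 577.

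Interferon response genes were higher in the megakaryocyte- and erythroid-like cells in 11 of 16 members (median 1.02), such as Isg20 (2.13) and Rsad2 (2.07), and quiescence genes in 8 of 11 (median 0.94), with Egr1 (3.10) and Cdkn1c (2.37). Of 5 measured lymphoid priming genes, Gata3 (2.63), Bcl11a (1.89) and Runx3 (1.03) were higher (median 1.03, and 0.16 with no gene filter). Glycolysis genes were lower in 6 of 14 (median -0.49), Pgam1 (-2.47) the lowest, and Hk1 (1.14) was higher. Oxidative phosphorylation had a median of -0.37. Cycling genes were near the background of the contrast, with medians of 0.21 for G2 and M phase and 0.12 for S phase. The median of all described genes was 0.21 to 0.24 here, and the medians of clonal hematopoiesis genes (0.40, Jak2 at 1.38), other remodelling factors (0.44) and splicing (0.22) lay above the middle 95% of random lists in every library. Medians that did not were 0.44 for histone and DNA modifying enzymes, 0.69 for immediate early genes, 0.20 for SRCAP complex and H2A.Z genes, with Znhit1 alone lower in 4 of 4 libraries, 0.33 for homologous recombination and Fanconi anemia, 0.42 for end joining, 0.29 for mismatch and excision repair, 0.32 for DNA damage signalling, 0.44 for p53 targets, 0.09 for MYC and ribosome biogenesis, 0.38 for MHC and 0.17 for apoptosis regulators. By library the MHC median was 0.53, 0.23, 0.65 and 0.00, and over libraries it was 0.23 without library 1 or library 3 and 0.76 without the highest doublet scores. The apoptosis regulator median was 0.10 without library 1 or library 4. With no gene filter the immediate early median was 0.35. The G2 and M phase median was -0.11 at a mitochondrial limit of 5%, and median-of-ratios scaling gave -0.04 for MYC and ribosome biogenesis, 0.02 for S phase, 0.05 for apoptosis regulators and 0.09 for SRCAP complex and H2A.Z genes.

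Differences between libraries within a class depended on the pair. Of 5965 genes in HSC-like cells, 13 differed at least 1.5-fold between libraries 3 and 4 and 204 between libraries 2 and 3, of which 186 were higher in library 2. Between libraries 2 and 3 the count was 310 of 5312 genes in B lineage-like and 442 of 5303 genes in dendritic cell-like cells. These counts rest on size alone and include counting error. Long genes stood higher in library 2. In HSC-like cells the 699 genes spanning at least 100 kb had a median log2 difference of 0.29 from the median of the other libraries, and the 1553 genes under 10 kb a median of -0.01. Library 3 went the other way, with -0.11 for the long genes. Kcnq1ot1, a long non-coding RNA, stood at 657 CPM in library 2 and at 355 to 405 CPM in the others. Relative to the median library, library 2 was higher for HSC-like DNA damage signalling (0.38), S phase (0.34) and other remodelling genes (0.27), while the SRCAP complex and H2A.Z list stood at 0.00, 0.04, -0.01 and 0.00 in libraries 1 to 4. In dendritic cell-like cells that list was at -0.12 in library 3. These are values of single libraries whose genotype is not known, with no test between them.

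**Figure D3:**
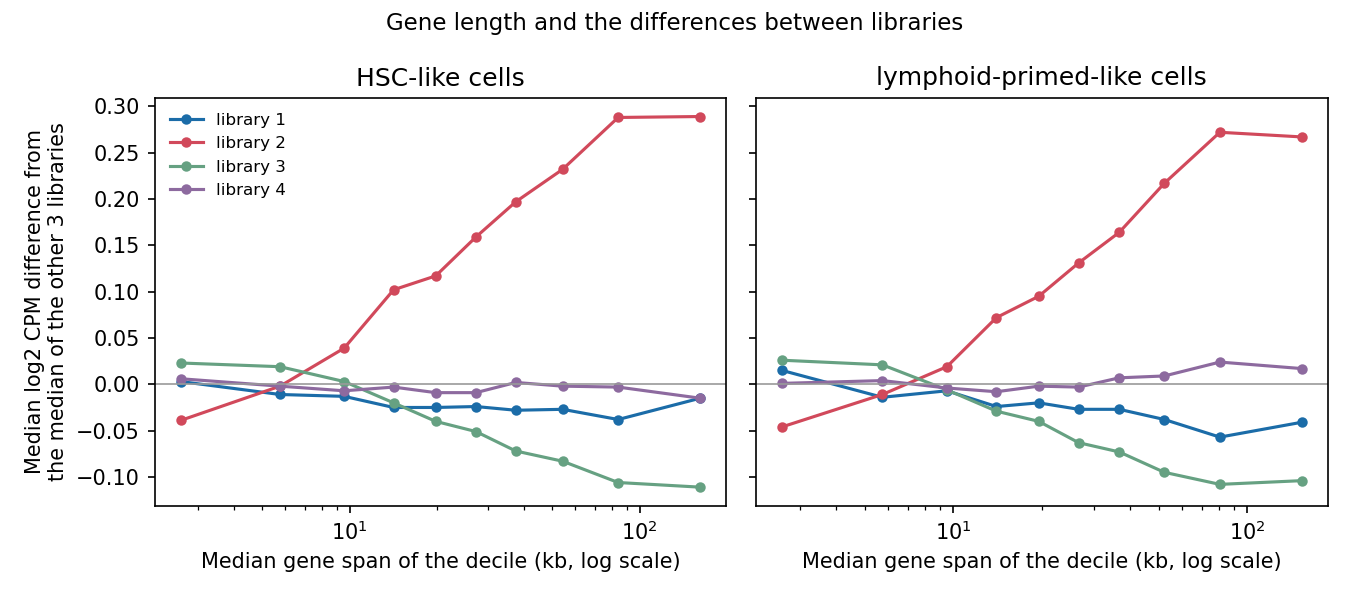
Median log2 CPM difference of each library from the median of the other 3 libraries against the median gene span of 10 groups of genes of equal number (kb, log scale), for HSC-like and lymphoid-primed-like cells; lines join the points of a library (barcode suffix) and there are no error bars. Library 2 lies above 0 and library 3 below it for the longest genes.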

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

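No paired analysis was possible because the cells carry no map to samples, so the replicate numbers could not be used. For the same reason the planned edgeR comparison of mutant with wild type and its alternatives (DESeq2, the replicate block, leaving out replicates, no low-count filter) were not run. The alternatives without the highest 8% of doublet scores and with only cells of few cell cycle UMIs were chosen after seeing the data; the latter left fewer than 50 cells on a side of the other contrasts and gave no value there. A list median counted as unmoved when it stayed inside the range of the 4 libraries, and the list medians below lay outside it. A share counted as moved when it differed from the reported median by at least the largest half-width of the 95% intervals of its 4 libraries. A list counted as reversed only where its 4 libraries had 1 sign and the alternative the other, so a sign change in a list whose libraries spanned 0 did not count as reversed. Where no construction is named, the cause was not tested.

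The HSC-like share was 15.1% at resolution 0.5, 9.84% at a mitochondrial limit of 5% and 10.5% with at least 1000 genes, and 11.3% to 13.9% with a library left out. The lymphoid-primed-like share was 1.49% at resolution 0.5, 12.1% at resolution 2, 13.3% with doublets kept, 8.47% with the second split of genes, 11.01% at the 5% mitochondrial limit, 11.2% with at least 1000 genes and 10.7% without the highest doublet scores. The megakaryocyte-like share was 8.44% at resolution 2, 9.28% with doublets kept and 10.7% without the highest doublet scores.

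HSC-like against other progenitor-like cells: with few cell cycle UMIs the medians were -0.04 for homologous recombination and Fanconi anemia, -0.17 for S phase, -0.47 for G2 and M phase and 0.28 for interferon response, and quiescence and cell cycle inhibitors (-0.071), p53 target genes (-0.12) and myeloid regulators and receptors (-0.22) reversed. At a pseudocount of 5 CPM they were -0.95, -1.84, -3.19 for the first 3 of these and 0.47 for quiescence and cell cycle inhibitors. The filter at 20 CPM gave homologous recombination and Fanconi anemia -0.66, G2 and M phase -4.38, quiescence and cell cycle inhibitors 0.091 and, reversed, non-homologous end joining 0.10. No filter reversed non-homologous end joining (0.004) and myeloid regulators and receptors (-0.14). Without the highest doublet scores homologous recombination and Fanconi anemia was -1.29, S phase -2.50, quiescence and cell cycle inhibitors 0.67 and interferon response 0.74. S phase was -2.50 with at least 1000 genes, and quiescence and cell cycle inhibitors 0.77 at resolution 2. Interferon response was 0.74 at resolution 0.5, 0.85 at resolution 2, 0.73 at the 5% mitochondrial limit and 0.73 with median-of-ratios scaling.

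Lymphoid-primed-like against neutrophil- and monocyte-progenitor-like cells: G2 and M phase was -3.30 at resolution 0.5, -0.044 at resolution 2, -2.94 with the second split and -2.56 at a pseudocount of 5 CPM, and reversed with doublets kept (0.16) and at the 5% mitochondrial limit (0.091). Lymphoid priming was 4.34 at resolution 0.5, 2.31 with doublets kept, 2.94 at the 5% mitochondrial limit, 3.12 without the highest doublet scores, 1.67 at a pseudocount of 5 CPM, 1.89 with the filter at 20 CPM and 2.34 with no filter. Myeloid regulators and receptors were -1.12 at resolution 0.5, -0.82 at resolution 2, -0.70 with the second split, -0.87 at the 5% mitochondrial limit, -0.82 without the highest doublet scores, -0.65 at a pseudocount of 5 CPM and -0.93 with the filter at 20 CPM. SRCAP complex and H2A.Z reversed at resolution 2 (0.073) and with doublets kept (0.042), and homologous recombination and Fanconi anemia at resolution 2 (0.017).

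Megakaryocyte- and erythroid-like against neutrophil- and monocyte-progenitor-like cells: interferon response was 1.08 without the highest doublet scores, 0.81 at a pseudocount of 5 CPM and 0.73 with the filter at 20 CPM. Myeloid regulators and receptors were -2.58 with doublets kept, -2.56 at the 5% mitochondrial limit, -2.58 without the highest doublet scores, -2.05 at a pseudocount of 5 CPM and -2.63 with median-of-ratios scaling. G2 and M phase reversed at the 5% mitochondrial limit (-0.11) and MYC and ribosome biogenesis with median-of-ratios scaling (-0.036). Leaving out a library cannot move a median outside the range of the libraries. Over all lists and the other alternatives, 171 values of the first contrast, 137 of the second and 191 of the third stayed inside that range, while 87, 100 and 48 moved and 6, 5 and 2 reversed. Srcap stood at a median of 56.0 CPM in kept cells and 56.7 CPM in all barcodes.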

Other observations

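The tests of gene length, of UMIs per cell and of genes per cell were chosen after their results had been seen, and that of Srcap among genes of like length after the length trend had been seen. Cell classes outside the contrasts had clear gene sets of their own among the genes kept out of the clustering. B lineage-like cells led with Lef1 (median log2 ratio to all other cells 7.08), Cecr2 (6.69), Bfsp2 (6.06), the surrogate light chain gene Vpreb2 (5.97) and Blnk (5.90), a signalling adaptor of B cells, and had the highest summed CPM of G2 and M phase genes of any class, with a median of 7772 against 174 in HSC-like cells. Dendritic cell-like cells led with Ifi205 (7.58) and Aif1 (7.36) and held the MHC class II genes H2-Eb1 (6.69) and H2-Aa (6.54). In plasma cell-like cells Ighm stood at 88065 to 116772 CPM in every library, while the switched classes differed from library to library. Ighg1 was at 0.539 CPM in library 1 and at 1623, 2125 and 2356 CPM in libraries 2 to 4, Ighg2c at 1446, 534, 1319 and 23.5 CPM and Ighg3 at 2695, 906, 14.7 and 618 CPM.

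Within HSC-like cells, library 4 had the highest levels of Vldlr (24.4, 27.4, 31.3 and 49.6 CPM in libraries 1 to 4), Clu (16.7, 16.5, 31.5 and 45.0 CPM), Neo1 (15.3, 17.1, 37.7 and 51.1 CPM) and Selp, the P-selectin gene (75.6, 83.2, 89.3 and 118.7 CPM). It had the lowest levels of the MHC class II genes Cd74 (446, 423, 265 and 192 CPM), H2-Aa (272, 258, 174 and 132 CPM) and H2-Eb1 (160, 162, 99.8 and 69.4 CPM). Gkn3 stood at 4.95, 8.11, 77.5 and 18.99 CPM.

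Homologous recombination and Fanconi anemia genes were lower in HSC-like cells, and fewer cycling cells among them is a candidate explanation. Among cells with few S and G2/M phase UMIs the homologous recombination and Fanconi anemia median was -0.04, inside the middle 95% of random lists in every library. Of the 24 members 12 passed the expression filter there, and these 12 had a median of -0.54 in all cells. Mismatch and excision repair kept a median of -0.14 over its 29 members. The S phase and G2 and M phase medians also stayed negative in these cells, so the restriction left some cycling difference. Whether that or another source accounts for the remainder was not tested. Whether repair genes differ with the Srcap genotype was not tested.

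Long genes were higher in library 2, and so was Srcap. Srcap spans 49237 bp, so it is not among the genes set apart above as long by span, and its longest transcript has 10654 bp. Spearman's rho across genes between span and the difference of library 2 was at least 0.496 in the 5 classes tested. It was 0.591 in unnamed progenitor-like cells and 0.425 in dendritic cell-like cells. With transcript length rho was higher than with span in all 7 classes examined, 0.627 against 0.515 in HSC-like cells. Srcap itself lay at percentile 98.3 of 237 genes with transcripts of like length, at a log2 difference of 0.61 against an upper bound of 0.58 for the middle 95%, so it passed that bound narrowly and length may not account for all of its level. The number of UMIs per cell is not a likely source, since the median of library 2, 10224, was 1 below that of library 3, 10225, which had the opposite trend. Reads per cell were not examined, so sequencing depth itself was not tested. Genes per cell did set library 2 apart, with medians of 2945, 3242, 2997 and 2985 in libraries 1 to 4 and, in cells thinned to 5000 UMIs, of 1917, 2055, 1907 and 1916. RNA quality, library complexity, sequencing depth and genotype stay open.

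The HSC-like share of library 4 was above the others. With the second split of genes it stayed 9.93 percentage points above the highest other library. Under stricter cell filters it stayed at least 1.82 times the highest other. This argues against the random choice of the other clustering genes and against these filters as the source. The cell type markers stayed in the clustering set under the second split, so their choice was not tested. The naming rule was the same throughout, so the border between HSC-like and unnamed cells was not tested. An unnamed cluster with 4 HSC markers at least 2-fold higher held 5.39%, 12.8%, 5.25% and 5.22% of libraries 1 to 4. Differences in sorting, in the recipient and in genotype stay open and were not tested.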
